A study of Caenorhabditis elegans with 4 samples.

How the data were processed

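Chromatin immunoprecipitation and sequencing (ChIP-seq) recovers the DNA fragments that are crosslinked to a protein and counts where in the genome they fall. Here it was applied to LET-418 in whole wild-type (N2) Caenorhabditis elegans at larval stage L3, grown at 20 °C. The 4 samples are 2 ChIP replicates and 2 input DNA samples, numbered 1 and 2 in the labels. Worms were crosslinked with EGS and formaldehyde and the chromatin was sonicated, per the labels' protocols. The labels describe an affinity-purified rabbit polyclonal antibody for the ChIP samples. Nothing in the labels says whether the replicates came from separate cultures.

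The data are 3 peak lists: 1 for each ChIP replicate and 1 series-wide list whose peak names carry no replicate. Peaks were called with MACS against the WormBase WS220 assembly, per the file headers and their source column. WS220 is the assembly that genome browsers call ce10, and ce10 and the aligner BWA are named in the submitters' processing notes. The versions of BWA and MACS, the calling threshold, the use of the input samples, any filter on repeats or duplicate reads, and the way the series-wide list was made are not given in the sources used here. Each peak has a start, an end and a score, which the authors deposited with 2 decimals and no named scale. The lowest score in any list was 1.31. The score is the authors' own and was ranked, divided, summarised and compared only within 1 list, except for a rank correlation of the scores of shared peaks between the replicates. The lists hold no read counts, so the sequencing depth is unknown and no depth could be set beside a peak. A longer list can come from deeper sequencing as well as from stronger enrichment. Intervals given for shares and densities cover counting error over peaks only.

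No list was filtered. Peaks were called shared where they overlapped by at least 1 bp. The overlap of the replicate lists was tested by rotating the replicate 1 list along each chromosome by random distances, which keeps peak widths and spacing, with 100000 rotations in the main tests and 10000 in the alternatives. Chromosome lengths were taken from the files as the end of the last peak in any list, so they are lower bounds. Scores of shared and unshared replicate 2 peaks were compared with a two-sided permutation test of the difference in medians (100000 permutations). The density of peaks on X was compared with that on the autosomes by two-sided Fisher's exact test against length in units of 1 kb, with an exact binomial interval for the ratio. The share of autosomal peak midpoints in the middle of 3 equal parts of each chromosome was tested with the same rotations (two-sided) and an exact binomial test. The 2 outer parts of a chromosome were compared by a two-sided exact binomial test of their counts and an exact sign test over the 6 chromosomes. Benjamini-Hochberg adjustment was made over the 3 lists. Shares carry 95% Wilson intervals and densities 95% exact Poisson intervals. Peaks lie in clusters and are not replicates. Where neighbours are called together, p-values from the Fisher, binomial and score permutation tests are too small. All intervals over peaks are then too narrow. The rotation tests allow for this clustering. A later comparison asked how often replicate 2 peaks were called in replicate 1 at a matched replicate 2 score, with a Mantel-Haenszel odds ratio over 20 score strata. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.

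The procedures were tested on simulated data. With unrelated lists of 1887 peaks the rotation test of overlap gave p of 0.05 or less in 2 of 100 simulations, and a list with 829 planted overlaps returned 829. A planted X to autosome density ratio of 0.5 was recovered with a mean of 0.502, and 93 of 100 intervals held it. The rotation test of the middle part gave p of 0.05 or less in 7 of 100 simulations of 1801 uniformly placed peaks. A planted stratified odds ratio of 3 was recovered with a median of 2.97. The simulated peaks were drawn independently of each other, whereas the real ones lie in clusters. The simulations therefore do not check error rates or interval coverage for clustered peaks.

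The planned tests of peaks at gene 5′ ends, annotation classes, gene lists and sequence motifs need gene models and sequence on WS220. The gene table at hand is on another assembly, WBcel235, so its coordinates were not set against the peaks and no peak was assigned to a gene. It served only to count protein-coding genes per chromosome. Of the rule fixed for naming genes, only the part on genes at the 20 highest-scoring series-wide peaks could be carried over, and examples of those peaks are named as regions. The widest peaks, the densest and sparsest 500-kb bins and the last 10% of V were chosen after their values were seen. The score-matched comparison, the comparison of both ends of each chromosome and its sign test, the comparison by score decile, the shares on X and in the middle part at equal list length and in the series-wide peaks that overlap both replicates, the rank correlation of scores, the X ratios per gene for each replicate and the count of peaks at chromosome ends were also added after the data had been explored. So were the sign test of the middle part and the overlap of the highest-scoring series-wide peaks with each replicate at equal list length. The other tests were set before any peak was examined. Alternatives covered the overlap that counts as shared, a stricter score threshold, equal list lengths, each replicate list alone and genes in place of length. The input samples are not analysed here on their own, since the lists used hold no value per input sample.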

Results

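LET-418 is a worm homologue of the chromatin-remodelling ATPase Mi-2/CHD4 and a subunit of the NuRD and MEC complexes. Its binding sites in larvae of stage L3 were mapped by ChIP-seq in 2 replicates, and the design asks where along the genome LET-418 lies and whether both replicates place it at the same sites. Replicate 1 had 1887 peaks, which covered 503 kb or 0.502% of the genome. Replicate 2 had 19594 peaks, 10.4 times as many, which covered 6632 kb or 6.61%. The series-wide list had 13690 peaks over 4600 kb, or 4.59%. Peaks were narrow in all 3 lists, with a median width of 208 bp in replicate 1, 249 bp in replicate 2 and 246 bp in the series-wide list, and no peak was under 146 bp. Wide peaks were few: 24, 566 and 393 peaks exceeded 1 kb in replicate 1, replicate 2 and the series-wide list. Each list is a single value per replicate, and the read depth behind it is unknown.

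Nearly all sites called in replicate 1 were also called in replicate 2. Of the 1887 replicate 1 peaks, 1868 overlapped a replicate 2 peak, which is 98.99% (95% Wilson interval 98.4 to 99.4). Random rotations of the replicate 1 list along the chromosomes gave 12.04% on average and 36.2% at most, and none of 100000 reached the observed share (one-sided permutation p = 1e-05, the smallest these rotations can give). In the other direction 1695 of the 19594 replicate 2 peaks, or 8.65%, overlapped replicate 1. Of the 19 replicate 1 peaks that were absent from replicate 2, 7 were in the last 10% of chromosome V, as were 159 of the 1868 shared ones. The 3 with the highest scores among them were V 19035411 to 19035701, V 19022428 to 19022631 and V 19025395 to 19025626, with scores of 9.21, 7.89 and 6.01 in replicate 1. The overlap was lower when both lists had the same length. Of the replicate 1 peaks, 46.6% overlapped the 1887 highest-scoring replicate 2 peaks, against 1.91% after rotation.

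Replicate 2 peaks that were shared with replicate 1 were stronger and wider than those that were not. Their median score was 35.1 (quartiles 21.2 and 55.8, 1695 peaks) against 8.52 (quartiles 5.0 and 16.7, 17899 peaks), a difference of 26.6 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). This permutation treats peaks as independent, which clustered peaks are not. The median width of the shared peaks was 383 bp against 241 bp for the others. The size of this gap depends on the overlap rule, since a wider peak meets a 1-bp overlap more easily. When 50% of the replicate 2 peak had to be covered, which a wider peak meets less easily, the medians were 289 and 245 bp. The shared part was 0.357% in the lowest decile of replicate 2 by score and 38.9% in the highest decile, so most of the strongest replicate 2 peaks had no counterpart in replicate 1. Across the 1868 shared replicate 1 peaks, which are not independent replicates, the scores in both replicates had a Spearman's rho of 0.41.

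The series-wide list was close to replicate 2 in extent. Of its 13690 peaks, 93.3% (12776) overlapped replicate 2 and 12.1% (1661) overlapped replicate 1. The replicate 1 share was 7.22% when 50% of the series-wide peak had to be covered and 23.3% among series-wide peaks at or above the median score. The series-wide list held 1883 of the 1887 replicate 1 peaks and 12402 of the 19594 replicate 2 peaks, so 7192 replicate 2 peaks had no series-wide counterpart. These had a median replicate 2 score of 5.18, against 15.2 for the replicate 2 peaks in the series-wide list. A further 899 series-wide peaks, 6.57%, overlapped neither replicate list (8.38% with the 50% rule, 2.28% at or above the median score), and their median series-wide score was 4.65 against 7.96 for the others. At the top of the ranking the series-wide list shared more with replicate 1: its 1887 highest-scoring peaks overlapped 73.3% of the replicate 1 peaks (Wilson 71.3 to 75.3) and 62.2% of the 1887 highest-scoring replicate 2 peaks (59.95 to 64.3).

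LET-418 peaks were unevenly spread over the chromosomes, and chromosome III carried the most in every list. The series-wide list had 199.4 peaks per Mb on III (exact Poisson interval 192 to 207), 169 on I, 146 on II, 119.01 on IV, 107 on X and 104.3 on V. Replicate 2 had 269 peaks per Mb on III and 148 on V, the lowest. Replicate 1 had 37.7 on III (34.6 to 41.1) and 4.85 on X (3.88 to 5.99), the lowest. The densest 500-kb bin of the series-wide list was III 1.5 to 2 Mb, with 271 peaks there, 122 in replicate 1 and 300 in replicate 2, against medians over all 197 whole bins of 58, 5 and 88. Next came II 1 to 1.5 Mb with 206 series-wide peaks, III 3 to 3.5 Mb with 184, III 2 to 2.5 Mb with 174, III 1 to 1.5 Mb with 158 and V 19.5 to 20 Mb with 157. The sparsest bin was V 17 to 17.5 Mb, with 3 series-wide peaks, 1 replicate 1 peak and 23 replicate 2 peaks. A nearby stretch from V 16000001 to 16500000 had 17, 0 and 27.

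**Figure D1:**
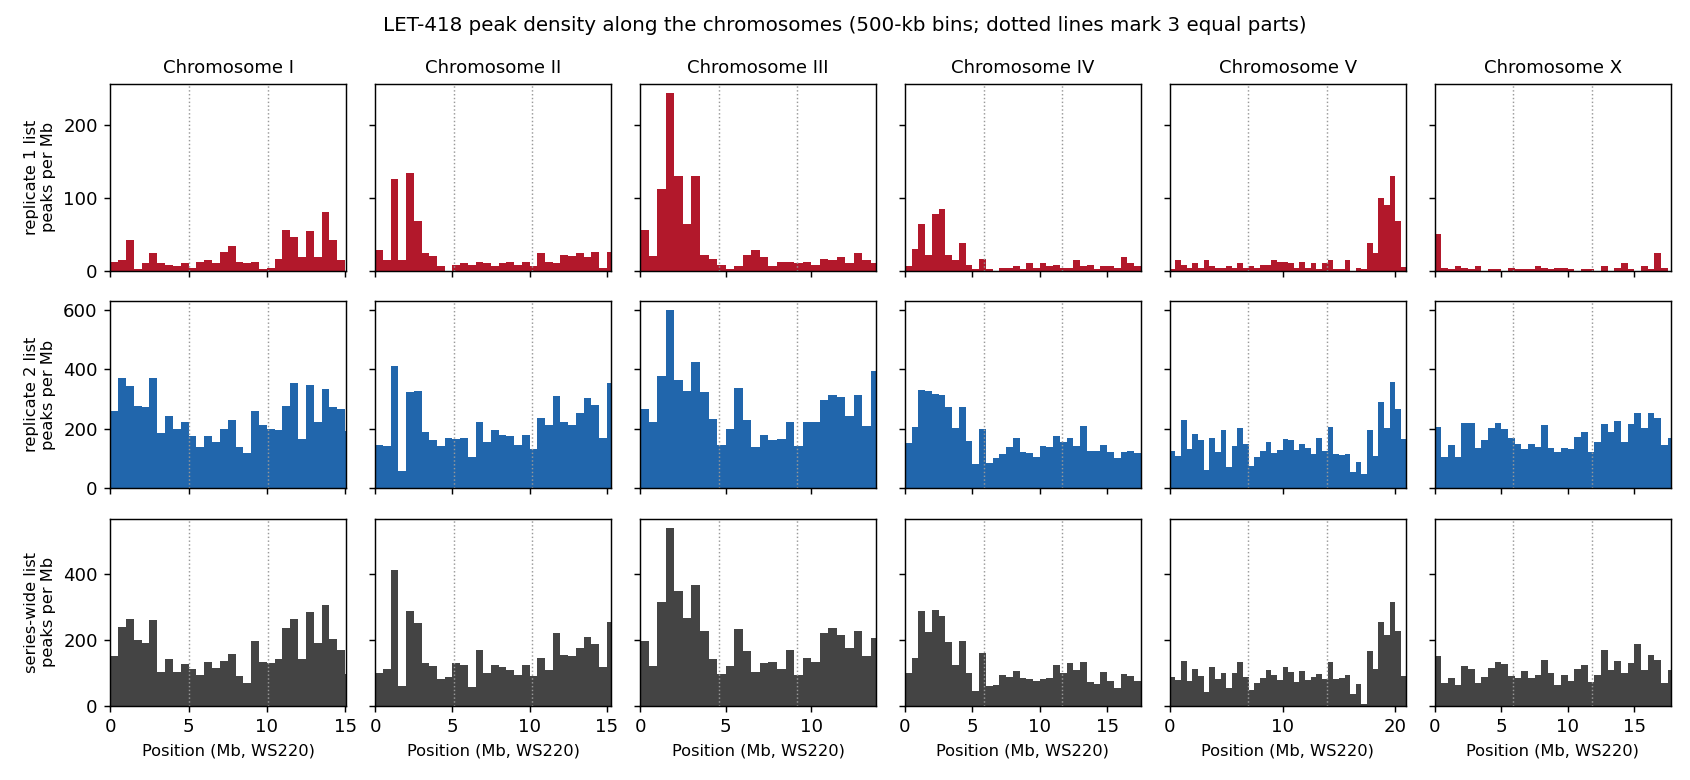
Peaks per Mb in 500-kb bins (vertical axis, a separate scale for each list) against position in Mb on WS220 (horizontal axis), for the replicate 1, replicate 2 and series-wide lists in rows and the 6 chromosomes in columns; dotted lines divide each chromosome into 3 equal parts. The highest bar of each list is the bin at III 1.5 to 2 Mb, with 122 replicate 1, 300 replicate 2 and 271 series-wide peaks, and the replicate 1 bars on X are low except in the first bin, which holds 25 peaks, and in the bin from X 16500001 to 17000000, which holds 12.

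The 20 highest-scoring series-wide peaks lay in the outer parts of the autosomes. All of them were called in both replicates, none lay in the middle of its chromosome, divided into 3 equal parts, and none lay on X. Of these peaks, 11 were on III between 1 and 3 Mb, 4 were on II, 2 on I, 2 on IV and 1 on V. The highest score, 55.2, was shared by II 732402 to 732778 (377 bp) and III 2126669 to 2127751 (1083 bp). A neighbouring pair on III, 1040510 to 1041701 and 1042143 to 1043019, followed at 54.92 together with III 2130050 to 2131804. The peak at III 1615879 to 1617131 had a series-wide score of 54.48 and overlapped the highest-scoring peak of replicate 2 (170.68). The sites elsewhere included IV 1624384 to 1624925 (53.34), I 11417139 to 11417688 (52.73) and V 19933060 to 19934131 (52.73). The last of these had a score of 5.29 in replicate 1, below the replicate 1 median of 5.32, and 152.91 in replicate 2. Over the highest score decile, a much larger group, the replicate 2 ranking was less one-sided than the series-wide one. X held 14.03% of the 1960 replicate 2 peaks of that decile and 4.97% of the 1369 series-wide ones. The middle parts held 24.2% and 12.5% of the autosomal peaks.

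The widest peak was on the right part of X. In replicate 2 it ran over 12428 bp from X 16929387 to 16941814, with a score of 111.42. The series-wide list had 2 neighbouring peaks there, of 6518 bp (X 16929431 to 16935948) and 6975 bp (X 16935999 to 16942973). Other wide replicate 2 peaks were II 1235682 to 1242880 (7199 bp), V 3434541 to 3441172 (6632 bp) and II 10541976 to 10548364 (6389 bp). The V site was also the widest in replicate 1, at V 3437410 to 3440195 (2786 bp), with a low score of 2.65 there.

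X carried fewer peaks per Mb than the autosomes in all 3 lists, and by far the fewest in replicate 1. The series-wide list had 1896 peaks on X, or 107 per Mb, against 143 per Mb on the autosomes, a ratio of 0.749 (95% interval 0.713 to 0.786). The ratio depended on the peaks taken from that list, with 0.277 for the 1887 highest-scoring ones and 0.219 for those in both replicates. For the whole lists it was 0.875 in replicate 2 (0.841 to 0.909; 3097 peaks on X) and 0.222 in replicate 1 (0.177 to 0.276; 86 peaks on X). Fisher's exact p adjusted over the 3 lists was 8.87e-30, 2.12e-10 and 2.56e-65 for the series-wide, replicate 2 and replicate 1 lists. X was the lowest of the 6 chromosomes only in replicate 1; V was lower in the series-wide list, and IV and V were lower in replicate 2. With the chromosome as the unit an exact one-sided test of X cannot give a p under 0.167. X has fewer protein-coding genes for its length (2730, against 17241 on the autosomes in WBcel235). Per gene, the series-wide ratio was 1.02 (0.967 to 1.07, Fisher's exact p = 0.64), that of replicate 2 was 1.19 (1.14 to 1.23) and that of replicate 1 was 0.302 (0.240 to 0.375). Per gene, X was below the autosomes in replicate 1, above them in replicate 2 and not distinguishable from them in the series-wide list. The replicates differed by more than counting error at equal list length: X held 4.56% of the replicate 1 peaks (Wilson 3.71 to 5.59) and 13.9% of the 1887 highest-scoring replicate 2 peaks (12.4 to 15.5), an odds ratio of 0.296 (0.227 to 0.383, two-sided Fisher's exact p = 8.98e-24). This test treats the lists as separate sets of peaks, although 46.6% of the replicate 1 peaks overlapped those replicate 2 peaks. Each replicate gave a single list, so the p-value does not measure variation between replicates.

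Chromosome centres held fewer peaks than an even spread gives. On the autosomes, 24.9% of series-wide peak midpoints lay in the middle part of the chromosome, divided into 3 equal parts (2940 of 11794), where an even spread gives 33.3%. Rotated lists gave 27.02 to 40.3% in 95% of cases (two-sided permutation p = 0.0093, adjusted over the 3 lists 0.014). The share was 26.3% in replicate 2 (permutation p = 0.0033, adjusted 0.0099) and 14.5% in replicate 1 (permutation p = 0.052, adjusted 0.052). Rotated replicate 1 lists varied more widely, from 15.9 to 54.9% in 95% of cases, and the observed share lay just below that range. The two-sided test counts rotated shares equally far from their mean on either side, and that range reaches further above the mean than below. The share was under 33.3% on each of the 6 chromosomes in every list (two-sided exact sign test, p = 0.031, for each list). This sign test takes shares under and over 33.3% as equally likely, which clustered peaks need not give, so its p may be too small. The middle part was not always far below both outer parts. In replicate 1 it held 58 peaks on V, above the left part with 47, and 68 on I, against 69. It was also near the lower outer part on IV (502 against 526) and V (612 against 639) in the series-wide list. The same held on IV in replicate 2 (767 against 788). V in replicate 1 was the only case where the middle part exceeded an outer part. The lists overlap, so the 3 results are not independent. Exact binomial tests, which treat peaks as independent, gave p = 1.17e-87, 2.32e-85 and 7.50e-74 for the series-wide, replicate 2 and replicate 1 lists.

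Each autosome had a crowded end in replicate 1, and X leaned to the left within counting error. It was the right part on I (174 peaks against 69 in the left part) and on V (246 against 47). It was the left part on II (218 against 89), III (399 against 65), IV (190 against 43) and X (41 against 29). The difference on X gave a two-sided exact binomial p of 0.19, and 25 of the 41 peaks lay in the first 500 kb. In replicate 2 the end crowded in replicate 1 also had more peaks on III (1600 against 1220), IV (1391 against 788) and V (1153 against 1022), but fewer on I (1314 against 1372), II (1051 against 1249) and X (1026 against 1179). The deficits at that end on II and X exceeded counting error (two-sided exact binomial p = 3.95e-05 and 0.0012), and that on I did not (p = 0.27). The excesses on III, IV and V exceeded it too. Cut to the length of replicate 1, the replicate 2 list had more at that end on 5 of 6 chromosomes (852 against 572 peaks in all), including I (112 against 100) and II (126 against 116), and fewer on X (94 against 97). These differences on I, II and X lay within counting error (two-sided exact binomial p of 0.45, 0.56 and 0.88). In the series-wide list the end crowded in replicate 1 had more on I, III, IV and V and fewer on II (832 against 839) and X (601 against 728). The deficit on X exceeded counting error and that on II did not (two-sided exact binomial p = 0.00054 and 0.88). The excesses on I, III, IV and V exceeded it too.

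Series-wide peaks of the highest score decile lay less often on X, and less often in the middle part of an autosome, than those of the lowest decile. X held 20.2% of the lowest decile of series-wide peaks by score (Wilson 18.1 to 22.4) and 4.97% of the highest decile (3.94 to 6.25). The middle parts held 30.6% (27.99 to 33.4) of autosomal peaks in the lowest and 12.5% (10.8 to 14.4) in the highest decile. In replicate 1 the X share was 9.52% (6.11 to 14.6) in the lowest and 2.12% (0.826 to 5.31) in the highest decile, and the middle share 25.15% and 7.03%. The spans were smaller in replicate 2, and the difference between lists in this relation was not tested. There X held 16.99% (15.4 to 18.7) and 14.03% (12.56 to 15.6), and the middle parts 29.2% (27.04 to 31.5) and 24.2% (22.2 to 26.3).

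**Figure D2:**
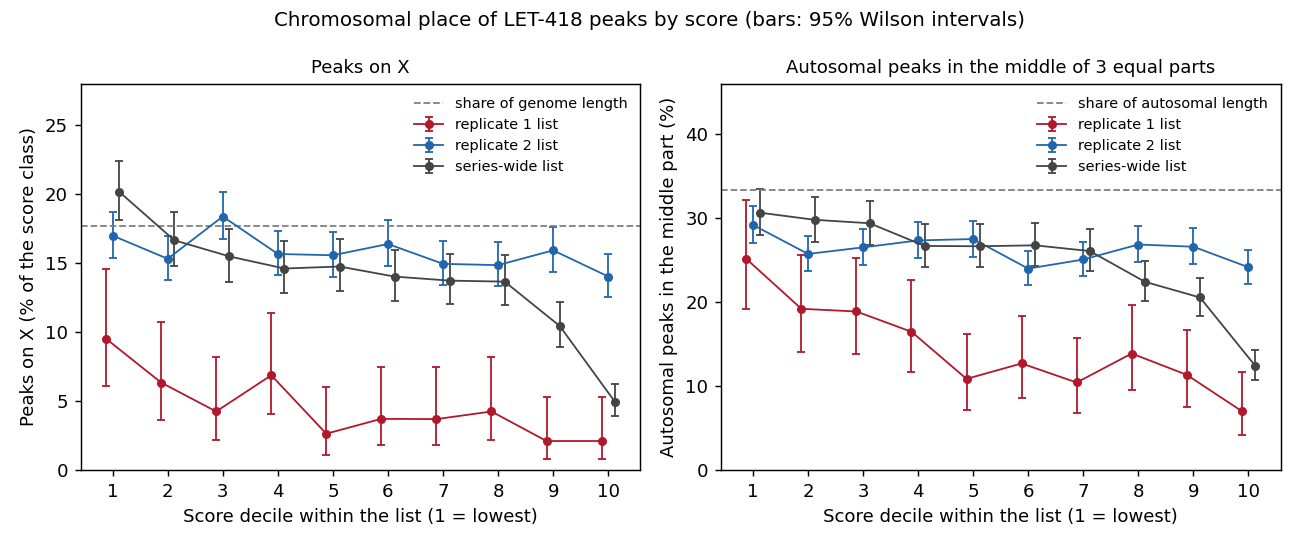
Share of peaks on X (left panel, percent) and share of autosomal peaks in the middle of 3 equal parts of the chromosome (right panel, percent) in each score decile of the replicate 1, replicate 2 and series-wide lists, with 95% Wilson intervals; dashed lines give the share of length, 17.7% for X and 33.3% for the middle part. The series-wide line ends at 4.97% on X and 12.5% in the middle part in the highest decile, and the replicate 2 line at 14.03% and 24.2%.

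At a matched replicate 2 score, a replicate 2 peak was called in replicate 1 with a probability that depended on its chromosomal place. In the highest score quintile, 48.9% (Wilson 46.4 to 51.4) of autosomal peaks at the crowded ends overlapped replicate 1. The value was 20.5% (18.05 to 23.2) at the opposite ends, 21.8% (19.1 to 24.7) in the middle parts and 8.86% (6.82 to 11.4) on X. Over 20 score strata the odds ratio was 0.196 for X against the autosomes (95% interval 0.153 to 0.251). It was 3.85 for the crowded against the opposite end (3.33 to 4.45) and lay above 1 on 6 of 6 chromosomes, from 2.52 on X to 4.85 on III. The crowded ends were taken from the replicate 1 list itself, so their direction is not independent evidence.

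**Figure D3:**
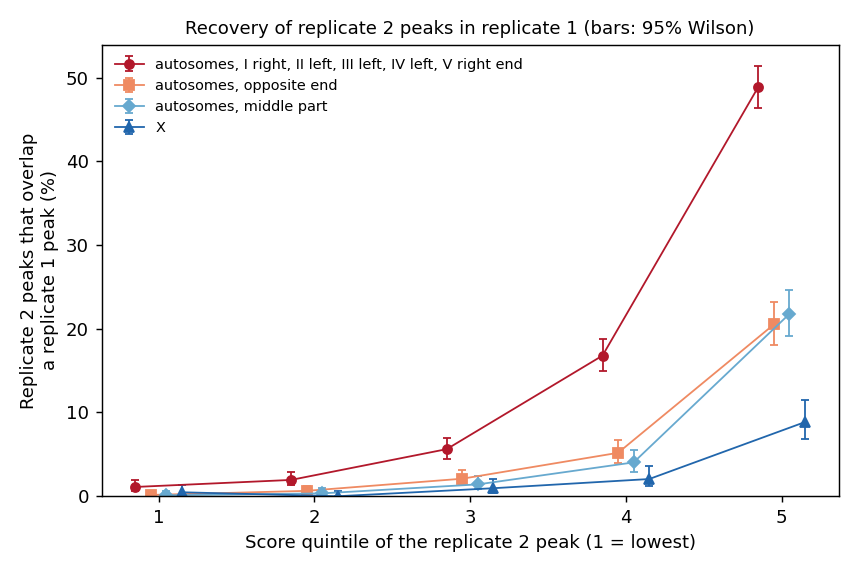
Share of replicate 2 peaks that overlap a replicate 1 peak (vertical axis, percent) by score quintile of the replicate 2 peak (horizontal axis, 1 is the lowest), for 4 chromosomal places, with 95% Wilson intervals. In the highest quintile the crowded autosomal ends reach 48.9%, the opposite ends and middle parts 20.5% and 21.8%, and X 8.86%.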

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

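The alternatives with equal list lengths for X and the centre, with peaks in both replicates, and with genes as denominator for each replicate were chosen after the data were seen. No paired analysis was possible because the lists hold no values per input sample, so a ChIP library cannot be set against the input of the same number. The overlap of the replicate lists stayed above every rotation, with 98.4% when 50% of the replicate 1 peak had to be covered, 57.4% when 50% of both peaks had to be, 98.7% between the stronger parts of both lists (scores at or above each median) and 46.6% with replicate 2 cut to 1887 peaks. The score difference of shared replicate 2 peaks was 24.4 with the 50% rule, and the width gap shrank to medians of 289 and 245 bp. The relation of the series-wide list to the replicates moved beyond counting error. With the 50% rule, 7.22% of its peaks overlapped replicate 1, 91.4% replicate 2, 7.04% both and 8.38% neither (12.1, 93.3, 12.02 and 6.57% with 1 bp); among peaks at or above the median score these were 23.3, 97.5, 23.1 and 2.28%. The X to autosome ratio of 0.749 lay between 0.222 and 0.875 when either replicate list was used alone, and was 0.219 for series-wide peaks in both replicates, 0.277 for the 1887 highest-scoring series-wide peaks, 0.587 at or above the median score and 0.751 for replicate 2 cut to 1887. It turned to 1.02 per protein-coding gene, with 1.19 for replicate 2 and 0.302 for replicate 1; the cause is the denominator, since X has fewer genes per Mb. The share of autosomal peaks in the middle part of 3 stayed under 33.3% in all alternatives, from 14.5 to 26.3% for either replicate alone. In replicate 1 (14.5%) it missed the threshold with a permutation p of 0.052, where the range of rotated lists is wide. The alternative with genes in place of length for the centre was not run, nor were the results that need WS220 gene models or sequence. The unknown read depth limits all comparisons of list length.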

Other observations

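The tests of list length and of pairing centres were chosen after the results were seen; the score-matched tests were set down before their values were computed.

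The low number of X peaks in replicate 1 (4.56%) is a difference between replicates of 1 group. List length alone does not account for it, because the 1887 highest-scoring replicate 2 peaks had 13.9% on X, above the upper bound of 5.59% for replicate 1. The 1887 highest-scoring series-wide peaks had 5.62% (Wilson 4.67 to 6.75), close to replicate 1, so a cut by score did lower the X share in that list. How that list was made, and with it the part that replicate 1 has in its scores, is unknown. Lower replicate 2 scores on X do not account for it either. At matched replicate 2 score, the odds of a call in replicate 1 were 0.196 times those of autosomal peaks (upper bound 0.251). Matching on replicate 2 score cannot exclude weaker X peaks in replicate 1 itself, since scores of shared peaks had a rho of 0.41 between replicates. Median scores on X and the autosomes were 3.75 and 5.4 in replicate 1, 6.425 and 7.93 in the series-wide list, and 8.95 and 9.46 in replicate 2. A different share of males, which have a single X, a different input or a different read background on X remain open and were not tested, since the lists hold no reads. The labels give a population of both sexes for each replicate and no share of males.

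The end crowded with replicate 1 peaks (right on I and V, left on II, III, IV and X) is the end that carries the meiotic pairing centre, the region through which homologous chromosomes pair, as known from C. elegans genetics. The replicate 1 list had more peaks at that end on 6 of 6 chromosomes (two-sided exact sign test, p = 0.031), but on X the difference lay within counting error (41 against 29 peaks, two-sided exact binomial p = 0.19). The series-wide list had more on 4 of 6 (exact sign test, p = 0.69) and its upper part, at or above the median score, on 5 of 6 (3458 against 1977 peaks, exact sign test, p = 0.22). Replicate 2 had more on 3 of 6, and on 5 of 6 when cut to the length of replicate 1 (852 against 572 peaks, exact sign test, p = 0.22). In the full lists the excess at that end exceeded counting error on 4 chromosomes series-wide and on 3 in replicate 2. The opposite end had more beyond counting error on X series-wide and on II and X in replicate 2 (two-sided exact binomial p = 0.00054, 3.95e-05 and 0.0012). In the cut list the differences on I and II lay within counting error (two-sided exact binomial p of 0.45 and 0.56). The 6 of 6 meets what was written down for this explanation, but the explanation was found from the same list, and the demand that each chromosome exceed counting error was added after the values were seen. A link to the pairing centre end stays a hypothesis that these lists leave undecided. Matching on replicate 2 score changed the odds of a replicate 1 call at that end little over all chromosomes. It cannot exclude stronger peaks there in replicate 1 itself, since scores of shared peaks had a rho of 0.41 between replicates. The ends were also picked from the replicate 1 list, so an odds ratio over 1 was largely fixed in advance. The odds ratio at matched replicate 2 score was 3.85 with a lower bound of 3.33. Over all chromosomes it was 3.93 before matching. Peaks at that end did score higher on III (median replicate 2 scores 12.72 and 8.27) and V (12.25 and 7.92), where matching lowered it from 5.88 to 4.85 and from 6.17 to 4.79. They also scored higher on I (9.57 and 7.665), where it went from 2.98 to 2.81, and on II (10.44 and 8.62), where it rose from 3.49 to 3.65. On IV, with medians of 9.57 and 9.43, it rose from 2.47 to 3.09. On X, with medians of 8.9 and 9.15, it rose from 2.35 to 2.52. The 899 series-wide peaks in neither replicate list leaned the same way, with 503 in the outer parts with the pairing centre and 242 in the opposite ones, on 5 of 6 chromosomes (exact sign test, p = 0.22), with X the other way (19 against 22). The series-wide list may rest in part on replicate 1 reads, so these peaks are not independent evidence. A regional difference in read background or in repeats that attract reads remains open and was not tested.

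Replicate 2 had a peak within 500 bp of the left end of 6 of 6 chromosomes, each starting at base 1, while replicate 1 and the series-wide list had a peak at 0 of 6. The scores of these peaks in replicate 2 ran from 7.8 to 42.46. The right ends were left out, because the chromosome lengths were themselves taken from the last peak. A rotation test of these ends was run and then dropped, since the ends had been singled out from the same list. No source of these peaks was tested.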
